A study of Drosophila melanogaster with 2 samples.

How the data were processed

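ChIP-seq of GFP-tagged lms protein was performed on 2 biological replicates of whole embryos, with an antibody against GFP. Per the labels, chromatin was sheared by sonication and the assembly was dm6. Aligner, peak caller, IDR settings and read depth were not given in the sources used here. Per the notes deposited with the files, peaks were called on each replicate and on both replicates together against the same control alignment, and the IDR list was derived from those lists. Each deposited list gave, for every peak, its interval, a signal value, a −log10 q-value and a summit offset. The deposited signal is a score of the authors' caller whose scale was not stated: its median was 50.7 in replicate 1 and 13.7 in replicate 2, a ratio of 3.71, so it was used only to rank peaks within a list. The deposited −log10 q-value was at its maximum of 4.37 for all 7521 IDR peaks and was not used for ranking. The 3 lists of 30000 peaks end at that number, so weaker peaks were not analysed here. The IDR list was found to be the 7521 peaks of highest signal of the pooled list. No peak ran past the end of a chromosome of the reference.

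Labels placed both replicates in 1 group, and replicate numbers came from the labels. Annotation was Ensembl release 115 (FlyBase release 6.54) and sequence was the release 6 reference genome, both on the coordinates of dm6. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Tests, gene lists, motifs, alternatives and the rule for named genes were fixed before the data were examined. Named are lms, the genes nearest by start site to the 10 highest IDR peaks, the 10 protein-coding genes with most summits in the gene or 2 kb upstream, and up to 4 bound members of highest signal per list. Positions around start sites, GC profiles, the weaker pooled peaks, dinucleotide shuffles and matching on neighbouring start sites were added after the peaks had been examined.

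Peaks were represented by their summits. Replicate overlap used summits within 150 bp among the 7521 highest peaks of each replicate, against 1000 shuffles of replicate 2 within chromosomes. Each summit was classed in the order promoter (within 500 bp of a TSS), 5' UTR, coding exon, 3' UTR, other exon, intron, intergenic, against 1000 sets of random positions on the same chromosomes. Gene lists were compared with 10000 random lists of protein-coding genes matched in 10 groups of length plus 2 kb, two-sided, with Benjamini-Hochberg adjustment over 13 lists and a threshold of 0.05. lms was in no list because the tagged transgene may add copies of its locus, whose number was not measured here. Its surroundings were compared with 10000 random draws of protein-coding genes. Motif presence in 101 bp summit windows was compared with flanks centred 500 bp away by an exact McNemar test, using the left flank for odd and the right for even ranks, with adjustment over 52 motifs. Hexamers found in at least 100 peaks were ranked by their ratio of summit to flank windows. Dinucleotide-shuffled copies of the summit windows were made 100 times. The permutation p-values measure the spread of random positions or lists. The exact McNemar p-values treat peaks as independent, although the 7521 IDR peaks lay in 7420 distinct intervals. Neither kind measures the spread between embryos.

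The tests were tried on simulated data. In 50 simulated peak sets with random positions 0 of 650 lists were called. With 90% of members bound, the muscle identity list was called in 30 of 50 simulated sets and the sarcomere list in 47 of 50. The simulated positions were uniform within chromosomes, whereas the real peaks were concentrated at promoters. These rates of calling need not hold for the real peaks. Of 7521 simulated peaks 60.3% were planted as shared and 61.0% were recovered as matched. Alternatives covered the peak set, each replicate alone, the matching rule, promoter width, gene window, length matching, motif window and flanks. The top of the pooled list could not serve as an alternative because it equals the IDR list.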

Results

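Binding of the homeodomain protein encoded by lms (lateral muscles scarcer, CG13424) was mapped by ChIP-seq in whole Drosophila melanogaster embryos. lms is known from a small set of larval body wall muscles, and its product carried a C-terminal GFP tag. Chromatin from pooled male and female embryos of a transgenic line, collected between 6 and 18 hours, was precipitated with an antibody against GFP. The ages are those of the source name; a separate age label gives a number of hours that does not match them. There was 1 group with 2 biological replicates, so no comparison between conditions was possible. The comparisons made were between the replicates, between peaks and the rest of the genome, and between gene groups. Each replicate list held 30000 peaks, as did the list called on both replicates together. The list that passed the irreproducible discovery rate (IDR) procedure, called the IDR list here, held 7521 peaks with a median width of 322 bp. Read depth was not given in the sources used here, so no interval based on reads was calculated. All coordinates are on dm6 and count from 1.

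The replicates shared most of their highest peaks. Of the 7521 highest peaks of replicate 1, 78.0% (5865 peaks) had a summit within 150 bp of one of the 7521 highest of replicate 2. Peaks shuffled within each chromosome matched in 1.69% on average (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give). Among the 500 highest peaks of each replicate the share was 86.6%. Of the 7521 highest peaks of replicate 1, 94.5% had a partner somewhere in the full list of replicate 2. Across the 5865 matched peaks the signals of the replicates had a Spearman rho of 0.855. This value is across peaks, which are not independent replicates. The promoter peaks of CG14100 and Ugalt and the peak inside ph-p ranked between 1 and 6 in each replicate. Over all 30000 peaks of each list the matched share was 49.7%. Both lists were called against the same control alignment, so their overlap was not independent of that control.

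Peaks lay at promoters more often than shuffled positions did. Of the 7521 IDR summits, 3451 (45.9%) were within 500 bp of an annotated transcription start site (TSS), against 13.6% of shuffled summits (central 95% of shuffles 12.8 to 14.3%, two-sided permutation p = 0.001, the smallest possible). The 7521 highest peaks of replicate 1 and of replicate 2 gave 45.8% and 48.3%. Coding exons away from start sites held 11 summits (0.146%, against 13.7% when shuffled), and 3' UTRs held 0.851% against 4.43%. Both shares were lower than chance (permutation p = 0.001). Introns held 36.7% against 39.6% and intergenic sequence 15.1% against 27.1%, each with a permutation p of 0.001. With promoters narrowed to 250 bp the intron share was 41.4% and no longer below chance (permutation p = 0.829). The 22479 weaker peaks of the pooled list had 27.5% of their summits at promoters.

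**Figure D1:**
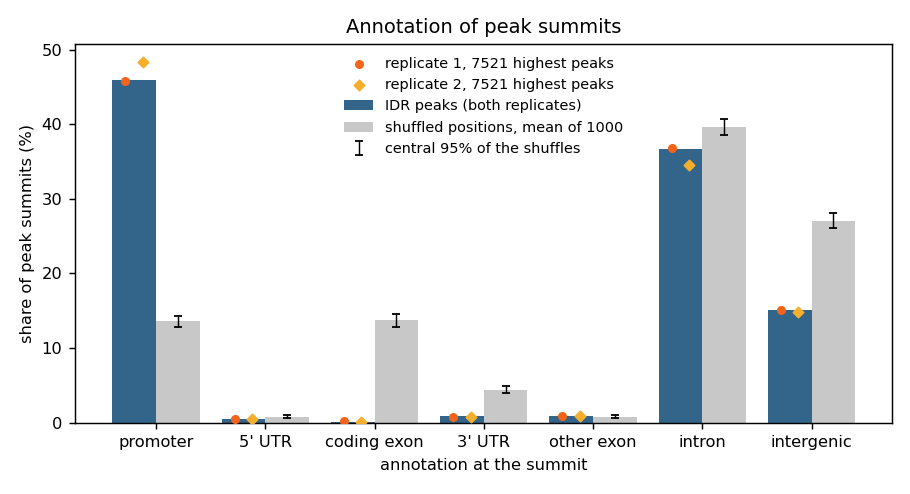
Share of peak summits (%) by annotation class for the 7521 IDR peaks (blue bars) and for shuffled positions (grey bars, error bars the central 95% of 1000 shuffles), with the 7521 highest peaks of each replicate as points. Promoters held 45.9% of IDR summits against 13.6% of shuffled positions, and coding exons 0.146% against 13.7%.

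Most promoter summits lay just upstream of the nearest start site. Of 3264 summits within 500 bp of a TSS of a protein-coding gene, 84.9% were upstream of it (exact 95% binomial interval 83.6 to 86.1%, counting error only). The median position was -117 bp, with quartiles at -202 and -47 bp. In each replicate alone the median was -114 bp. The peaks of CG18549 and Fkbp14 were typical of this placement, at 124 and 121 bp upstream of a start site; that of Fkbp14 lay inside the gene, before an internal start site.

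**Figure D2:**
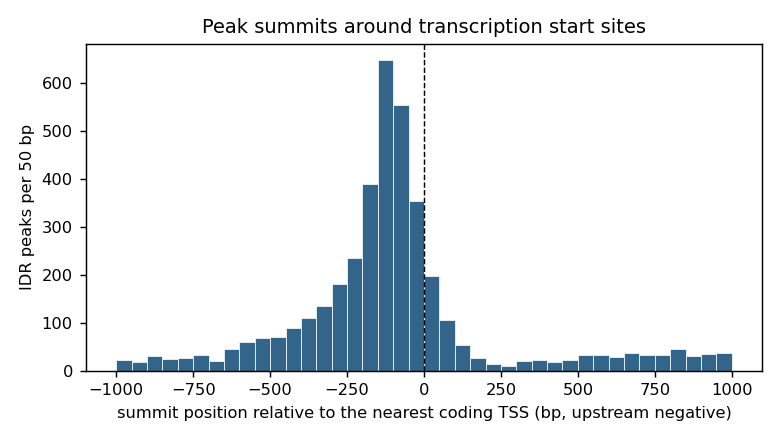
Number of IDR peak summits per 50 bp (vertical axis) by position relative to the nearest protein-coding TSS (horizontal axis, bp, upstream negative; dashed line, the TSS). Most summits within 500 bp of a TSS lie upstream, with a median at -117 bp.

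The 10 highest peaks lay mostly at promoters, with others in introns and in an exon of a noncoding gene. The top peak (signal 10625) lay on 3L from 19590365 to 19590862, with its summit 99 bp upstream of CG14100, and ranked first in both replicates. The next (2R, 15217536 to 15218022, signal 9119) was 139 bp upstream of mRpL41, which encodes a protein of the mitochondrial large ribosomal subunit. An intron of CG11050 held the third (2L, 6612346 to 6612995, signal 8929). The promoter of Ugalt, encoding a Golgi nucleotide sugar transporter, followed with 8685, a peak also in the window of the translation initiation gene eIF2Bbeta. ph-p, a Polycomb group gene, carried a peak of 7136 within 500 bp of a start site (X, 2137097 to 2138187). Art3, which encodes a predicted arginine methyltransferase, had a promoter peak of 7115. The peak of 6535 nearest to lncRNA:CR44619 had its summit in an exon of another noncoding gene, lncRNA:Vinr. CG18549 (6489, promoter), the kinase gene Lk6 (6437, intron) and Fkbp14 (6326, promoter) completed the 10 highest. All 10 ranked between 1 and 14 in each replicate list. Signal is the authors' own score for a peak and is used here only within 1 list.

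Several long genes held many peaks. kirre, which encodes an adhesion protein of muscle founder cells, had 30 IDR summits across its 394 kb and the 2 kb upstream. In the 7521 highest peaks of the replicates it had 31 and 28. CG1677 followed with 21. CG32264, mam (a coactivator of Notch), sbb and shn (a zinc finger protein of Dpp signalling) had 15 each. Tlk, tara and ush had 14 each, and Ten-a had 13. Per 10 kb, tara was densest of these 10 genes with 3.82 summits, and Ten-a was lowest with 0.443. Windows of genes that overlap or are nested share summits, so these counts are not exclusive to the gene named.

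lms itself carried no peak in the gene or the 2 kb upstream (2R, 20556877 to 20559953). Within 20 kb there were 4 IDR summits, against a median of 3 around random protein-coding genes (one-sided permutation p = 0.461). These lay 4741 bp to the left of lms, and 2456, 11417 and 12706 bp to its right in ascending coordinates. The nearest was inside the antisense gene asRNA:CR44653, and the last 2 were in an intron of qsm. Their signals ran from 241 to 375, with ranks from 2597 to 4189 in the IDR list. No excess of peaks around lms was detected by this test.

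Gene groups were compared by the number of members with an IDR summit in the gene or 2 kb upstream, called bound here. Of 13968 protein-coding genes 5583 (39.97%) were bound. Of the 13 lists, 1 differed from random genes matched on length (permutation test, Benjamini-Hochberg over the 13 lists). Ribosomal protein genes were that list: 77 of 92 were bound, against 27.4 in matched random lists (central 95% of lists 19 to 36, adjusted permutation p = 0.0013). The raw p of 1e-04 was the smallest that 10000 lists can give. The replicates alone gave 72 and 81 bound members. RpL34b (signal 1886, rank 227) and RpS20 (signal 1308, rank 439) had their highest peaks at promoters, at -134 and -159 bp from the nearest coding start site. The peak of RpS28b (1083) lay 760 bp from its own nearest start site, at the promoter of a neighbouring gene, and that of RpS3 (1646) lay upstream of the gene in an intron of a neighbouring gene.

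Neither list of muscle regulators passed the threshold, although single members carried high peaks. Of 20 transcription factors of muscle identity 10 were bound, against 12.2 expected (adjusted permutation p = 0.658). org-1, a T-box gene of muscle founders, had a promoter peak of 1749, and Poxm one of 1236. nau, the fly MyoD homologue, had 381 in an intron and sd had 248. The nau peak lay 4244 bp from its own nearest start site and 2586 bp from a coding start site of another gene. No summit lay in the windows of ap, slou, Kr, eve or vg, which were picked out after their values were seen. Of 18 mesoderm and heart regulators 12 were bound, against 9.71 expected (adjusted permutation p = 0.658). Assigned by the nearest start site, 13 were bound, against 8.08 (adjusted permutation p = 0.107). Within 500 bp of a TSS 5 were bound, below the 6.47 expected (adjusted permutation p = 0.870). The highest peak here (signal 5244, rank 19) was in the window of Mef2, a central factor of muscle differentiation, which held 9 summits. It lay 1057 bp upstream of the nearest start site of Mef2, at the promoter of neighbouring genes. zfh1 (1441), the heart factor tin (1281) and the visceral mesoderm factor bin (1251) were also bound.

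None of the 3 lists of muscle building genes passed the threshold. In the myoblast fusion list 12 of 18 members were bound, against 10.3 expected (adjusted permutation p = 0.734), led by kirre (1313), Hem (1172), mbc (824) and siz (690). For muscle attachment and guidance the count was 13 of 16, against 9.90 (adjusted permutation p = 0.313). Its highest members were stck (1101), rhea, which encodes talin (936), sli (680) and the integrin gene mew (653). The mew peak lay inside the gene, 22927 bp from its own nearest start site and 2310 bp from a coding start site of another gene. Without matching on length this list passed the threshold (adjusted permutation p = 0.00563). Sarcomere genes were bound in 8 of 23 cases, against 12.3 (adjusted permutation p = 0.257). sls, which encodes a titin-like protein, had a promoter peak of 1725. Act87E (751), Tm1 (683) and Actn (532) followed, and Mhc, named after its value was seen, had no summit. The Actn peak lay 858 bp from its own nearest start site, at -141 bp from a coding start site of another gene.

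None of the 4 lists for other cell types of the embryo passed the threshold. Of 17 neuronal markers 10 were bound, against 10.1 (adjusted permutation p = 1), with elav at 3289 (rank 60), scrt at 859, cpo at 519 and nSyb at 515. The nSyb peak lay 1809 bp from its own nearest start site, at -150 bp from a coding start site of another gene. Of 9 glial markers 6 were bound, against 4.89 (adjusted permutation p = 0.734), with moody at 1959, Gli at 748, pnt at 569 and loco at 313. Epidermal and tracheal genes gave 6 of 13, against 7.48 (adjusted permutation p = 0.734), led by trh (1552), grh (1250), ovo (716) and knrl (303). Gut, fat body and blood genes gave 9 of 15, against 8.78 (adjusted permutation p = 1), led by ush (6197, rank 11), Hnf4 (1292), fkh (554) and NimC4 (334). The ush peak lay inside the gene, 4873 bp from its own nearest start site and at -1405 bp from a coding start site of another gene.

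Segmentation, signalling and Hox genes did not pass the threshold as lists. Of 17 segmentation genes 3 were bound, ptc (522), inv (414) and hry (154), against 8.05 expected (raw permutation p = 0.0119, adjusted permutation p = 0.0773). In the highest peaks of replicate 2 alone 2 were bound, hry not among them, and the list passed (adjusted permutation p = 0.0136). Assigned by the nearest start site, 10 of 17 were bound, against 6.40 expected (adjusted permutation p = 0.232), and with matching on neighbouring start sites the expectation was 5.18 (adjusted permutation p = 0.693). Signalling genes were bound in 20 of 24 cases, against 15.3 (raw permutation p = 0.046, adjusted permutation p = 0.199). They were led by aos (2118), brk (1651), spi (1619) and Mad (1536), which act in EGFR and Dpp signalling. That list passed when genes were assigned by the nearest start site (22 of 24, adjusted permutation p = 0.00195) or without length matching (adjusted permutation p = 0.00065). Within 500 bp of a TSS 8 of 24 were bound, below the 9.25 expected (adjusted permutation p = 0.870). Of 8 Hox genes 5 were bound, against 5.43 (adjusted permutation p = 1), led by Abd-B (1221), Antp (821), Dfd (325) and pb (199). The central 95% of matched lists reached 8 bound members, so the test could not have detected an excess in this list.

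**Figure D3:**
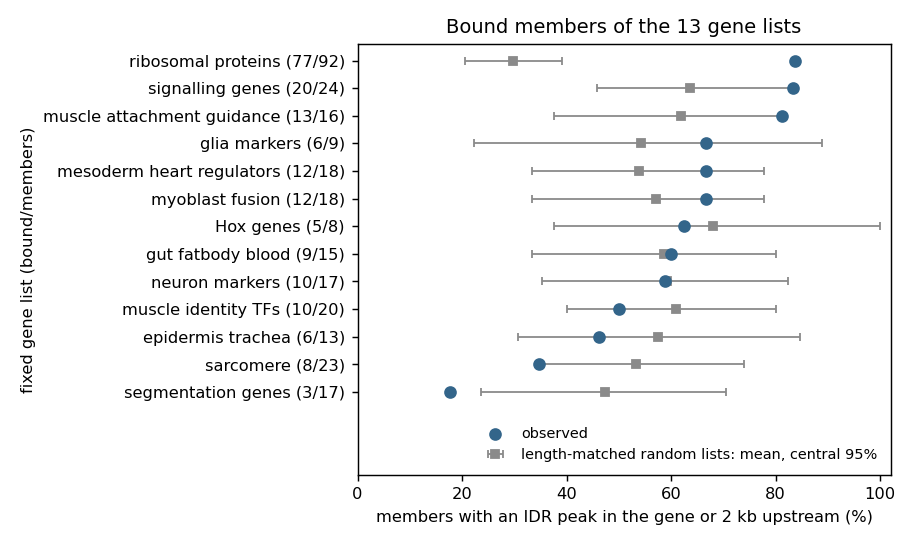
Share of the members of each of the 13 gene lists with an IDR peak in the gene or 2 kb upstream (horizontal axis, %; blue points), with the mean and central 95% of length-matched random lists (grey squares and bars). Ribosomal protein genes (77 of 92) lie outside their bar by the widest margin and are the 1 list past the threshold; segmentation genes (3 of 17) lie below their bar without passing after adjustment.

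Sequence at the summits was rich in A and T. Mean GC content in 51 bp windows was 31.5% at IDR summits and 44.5% at 300 bp to the left in genome coordinates, with 42.1% over the 7 chromosomes and arms. At the 1000 highest peaks it was 27.5%, and at the weaker pooled peaks 39.6%. TAATTA, the core that many homeodomains bind, was found within 50 bp of 11.3% of summits and in 5.78% of flanks, a ratio of 1.96 (exact McNemar test, adjusted exact p = 2.05e-41 over 52 motifs). The other 35 hexamers made of A and T alone had a median ratio of 2.36. TAATTA ranked 32 of these 36 and 121 of 2063 hexamers, which ATATTA headed with 3.20. Against dinucleotide-shuffled copies of the same windows, TAATTA was rarer than in the shuffled copies (11.3% against 14.3%, ratio 0.795), so the direction depended on the background.

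**Figure D4:**
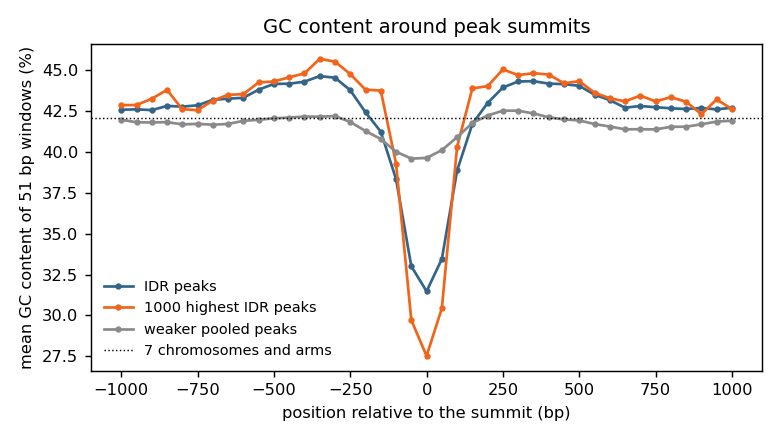
Mean GC content of 51 bp windows (vertical axis, %) by distance from the summit (horizontal axis, bp) for the IDR peaks, the 1000 highest of them and the weaker pooled peaks; the dotted line is the value over the 7 chromosomes and arms. GC content is lowest at the summit, with 31.5% for IDR peaks and 27.5% for the 1000 highest.

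Core promoter sequences stood out among the motifs fixed beforehand. TATCGATA, the element recognised by DREF, was in 1.58% of summit windows and 0.253% of flanks (ratio 6.26, adjusted exact p = 3.72e-21). GGTCACAC, the core of the element recognised by M1BP, was in 0.851% against 0.233% (ratio 3.66, adjusted exact p = 9.70e-09). At peaks over 500 bp from any start site TATCGATA had a ratio of 0.941 and GGTCACAC a ratio of 1.71, neither past the threshold. GGTCACAC also missed it in the higher-signal part of the IDR list (ratio 1.63, adjusted exact p = 0.177). The Mef2-type sequence YTAWWWWTAR was in 8.34% against 2.75% (ratio 3.04, adjusted exact p = 4.98e-61), and in 7.95% of dinucleotide-shuffled windows. GAGAGAG (ratio 0.273) and CACACACA (ratio 0.288) were less frequent at summits than in flanks, with adjusted exact p of 4.71e-19 and 2.01e-28. Neither was compared with dinucleotide-shuffled windows. The lowest ratio of the ranked hexamers was that of GGAGGA (0.125), so an effect of the low GC content of summits was not told apart.

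The X chromosome carried slightly more IDR peaks per Mb than the large autosome arms. X had 61.0 per Mb, 2L 58.4, 2R 51.6, 3L 56.7 and 3R 55.6. Chromosome 4 had 21.5 per Mb and Y had 0 peaks. Lengths were those of the whole assembled sequence, and the part of it to which reads can be mapped was not measured. The X to autosome ratio was 1.10 (exact 95% binomial interval 1.04 to 1.16, counting error only). The 7521 highest peaks of replicates 1 and 2 each gave 1.09. Over the full lists of 30000 peaks the ratio was 1.08 (1.04 to 1.11) in replicate 1 and 0.914 (0.886 to 0.942) in replicate 2.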

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

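The comparison of TAATTA with dinucleotide-shuffled windows, that of IDR peaks with weaker pooled peaks and the matching of gene lists on neighbouring start sites were chosen after the results were seen, and the other alternatives were planned. Of 41 alternative values for the 7 main results, 34 kept their direction and side of the threshold or stayed within the range set for them. The promoter share ran from 35.9% (250 bp) to 56.4% (1 kb) and stayed above chance, and replicate overlap ran from 49.7% (all peaks) to 83.1%. The number of gene lists past the threshold ranged from 1 to 2 with 1 replicate left out, and was 2 with assignment to the nearest start site and 3 without length matching, against 1. Ribosomal protein genes passed in each of these settings. The rank of TAATTA among hexamers was 59 in the higher-signal part of the IDR list and 191 at peaks over 500 bp from any start site, and the cause was not tested. Its ratio reversed to 0.795 against dinucleotide-shuffled windows, whose base composition matches the summits by construction. The intron share reversed to 41.4% with 250 bp promoters, which leave more summits to introns by construction, and TATCGATA reversed to 0.941 at peaks far from start sites, with the cause not tested. Within 10 kb of lms there were 2 peaks, on the other side of the random mean (permutation p = 0.534). TAATCC, not past the threshold in the main test, went from 0.887 to 1.04 in the higher-signal part, 1.08 far from start sites and 0.940 to 1.01 with 1 replicate left out. Gene lists changed sides of their expectation in 23 of 104 alternative values, none of them past the threshold. With the nearest start site these were muscle identity (11), neuronal (9), epidermal (7), Hox (6) and segmentation (10) genes, and within 500 bp of a TSS mesoderm (5), fusion (6), gut (5) and signalling (8) genes. Without length matching they were muscle identity (10), neuronal (10), epidermal (6) and Hox (5) genes, and with neighbour matching neuronal (10), epidermal (6) and Hox (5) genes. The higher-signal part moved fusion (7) and gut (6) genes, the 5 kb window Hox genes (6), leaving out replicate 1 neuronal (11), glial (4) and gut (9) genes, and leaving out replicate 2 Hox genes (6). Of 119 alternative values for the other 17 fixed motifs 7 lost the threshold, 7 gained it, 4 changed direction and the rest did neither. The peak count of the 70 named genes stayed within 1.5 times its value for 59 genes without replicate 1 and for 67 without replicate 2. It did so for 62 genes with the 5 kb window. In the higher-signal part of the IDR list, which holds fewer peaks by construction, it did so for 36. Selecting the highest pooled peaks was not run because it returns the IDR list. The unknown depth and the end of each list at 30000 peaks limit what can be said of weak sites.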

Other observations

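The X to autosome ratio of the highest peaks of each replicate was planned, and its use against a shift of X, like the other tests reported here, was chosen after the results were seen. Mitochondrial ribosomal protein genes were also bound more often than matched genes: 50 of 73, against 18.0 in length-matched lists (adjusted permutation p = 0.000467 over 14 families). Their highest peaks were at mRpL41 (9119), mRpS10 (7115, the peak it shares with Art3) and mRpS23 (4110). Chemoreceptor genes were bound less often than matched genes (11 of 179, against 64.2, adjusted permutation p = 0.000467), as were Cyp genes (11 of 85, against 33.8, adjusted permutation p = 0.000467) and Cpr cuticle genes (8 of 70, against 21.4, adjusted permutation p = 0.00105). Odorant-binding protein genes gave 6 of 51, against 12.5 (adjusted permutation p = 0.0966). Random lists were drawn gene by gene, whereas neighbouring members of a family can share a summit, as Obp83ef and Obp83g did. The permutation p-values of the 14 families may therefore understate the spread.

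Chromatin regulators carried some of the highest peaks without passing the threshold as groups. Of 14 trithorax group genes 12 were bound, against 8.33 (adjusted permutation p = 0.113), with Trl at 5389, brm at 3747 and osa at 3418. The osa peak was classed as promoter, within 500 bp of a start site of a noncoding gene. It lay at -13496 bp from the nearest coding start site. Of 16 Polycomb group genes 11 were bound, against 8.70 (adjusted permutation p = 0.388), with ph-p at 7136 and phol at 2976. Nuclear receptors gave 15 of 21, against 12.4 (adjusted permutation p = 0.385), with Hr3 at 3395. The E(spl) genes, targets of Notch, gave 6 of 11, against 2.54 (adjusted permutation p = 0.0622).

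TAATTA was more frequent at summits than in flanks. Recognition of this core by the tagged protein at most peaks was argued against, because 11.3% of summits had TAATTA within 50 bp. Its rank of 32 among 36 hexamers made of A and T was known before a rule for it was set, so the rank is no test. The AT-rich composition of the summits may account for the excess, since TAATTA occurred at 0.795 times its share in dinucleotide-shuffled windows. Binding at a smaller set of peaks stays open.

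Ribosomal protein genes were bound more often than matched genes. Gene-dense neighbourhoods were argued against, because matching on neighbouring start sites raised the expectation only to 30.6 of the 77 bound members. Promoters of broadly active genes in general had been predicted to bring most of 6 other housekeeping families past the threshold, and 1 passed. Proteasome (18 of 48, against 15.03), complex I (17 of 40, against 12.2) and translation initiation (20 of 44, against 18.0) genes did not pass. Nor did chaperonin (5 of 8, against 3.23) and vacuolar ATPase (13 of 33, against 12.02) genes. By the rule set beforehand, so few passing families counted against this cause in its general form. The counts of the families that did not pass were above expectation, but within the spread of random lists. Their adjusted permutation p ran from 0.188 (complex I) to 0.848 (vacuolar ATPase). Chemoreceptor, Cyp and Cpr cuticle genes were below expectation, so a weaker preference for promoters of broadly active genes stays open. Binding of the tagged protein at the promoters of ribosomal protein genes may explain the pattern as a hypothesis. Precipitation at them without the tagged protein stays equally open, since no untagged embryos were analysed here. Signal at any strongly transcribed locus also stays open: 9.66% of 290 tRNA genes had a summit within 500 bp (exact 95% binomial interval 6.51 to 13.7%), on the upper bound of shuffled summits (9.66%), and neither their transcription nor the mapping of reads to their copies was measured here.

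The full list of replicate 2 had an X to autosome ratio below 1, unlike that of replicate 1. A shift of X at all signal levels was argued against, because the highest peaks of replicate 2 gave 1.09, inside the interval of replicate 1. Weak background that follows chromosome copy number stays open: peaks without a partner in the other replicate had lower ratios than those with one, 0.706 (0.673 to 0.740) against 1.15 (1.10 to 1.19) in replicate 2 and 1.01 (0.969 to 1.05) against 1.14 (1.10 to 1.19) in replicate 1. It had been predicted to hold the intervals of both unshared ratios below 1, and an interval reaching 1 in either replicate was to count against it. By that rule the prediction failed in replicate 1, whose interval included 1. Replicate 2 met its part, so the 2 replicates together do not settle the explanation. No biological explanation was tested.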
